A study of Mus musculus with 36 samples.

How the data were processed

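Expression was measured by RNA sequencing in 3 brain regions of adult male C57BL/6 mice, the nucleus accumbens (NAc), the prefrontal cortex (PFC, its medial part in the series description) and the periaqueductal grey (PAG), after sham surgery or spared nerve injury (SNI). SNI cuts branches of the sciatic nerve and leaves another intact, and is a standard rodent model of lasting neuropathic pain. Tissue was taken 2.5 months after surgery. Each of the 6 combinations of region and surgery had 6 libraries, 36 in all. Per the labels' protocols, polyadenylated RNA was selected with poly-T beads and libraries were made with an Illumina TruSeq RNA kit from pooled RNA. The labels do not say which mice or how many stand behind a library, nor whether the 3 regions came from the same mice. P-values therefore measure the spread between these libraries, which may be partly technical. The groups shared no replicate numbers, and no pairing was used.

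The authors deposited 1 table of RPKM values (reads per kilobase of gene per M, or mega, assigned reads) for 31554 genes with a length for each gene. Per the submitters' processing notes, TopHat2, HTSeq and the mouse genome build mm10 were used; their roles, order, versions and settings are not given in the sources used here, and neither is the strand setting of the counting. Overlapping and antisense genes, and genes with near-identical copies such as ribosomal protein genes with processed pseudogenes, are therefore uncertain. Multiplied by length and depth, 100% of the deposited RPKM values gave whole reads within a tolerance of 0.001, which recovered the depth of every library. Libraries held 27.6 to 64.9 M assigned reads, so that 1 read of a gene of 1 kb was worth 0.0154 to 0.0362 RPKM. At 0.5 RPKM such a gene had 13.8 reads in the shallowest library, a counting error of 26.9%. Small RNA genes took at most 0.0298% of the reads of a library. Over 90 pairs of libraries of 1 group, the lowest chi-square per degree of freedom was 3.89, so no 2 libraries were copies of each other. Gene coordinates, biotypes and GC content came from GENCODE M21, on the same genome build; 97.9% of the gene identifiers matched it. GC content was that of the longest annotated transcript.

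RPKM values are not counts, so groups were compared with limma 3.58.1 (R 4.3.3), a linear model with moderated errors and a mean-variance trend, on log2(RPKM + 0.5). Fold changes on this scale understate those of low genes. Each SNI comparison used the 12 libraries of a region and genes with a mean of at least 0.5 RPKM over them. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A looser count used an unadjusted p under 0.05 and a fold of at least 1.3. Differences of SNI effects between regions, and sham against sham comparisons between regions (fold of at least 2), came from 1 model of all 36 libraries. For a few values, the difference of the SNI and sham means was tested by exact permutation over all 924 assignments of 12 libraries.

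A total of 44 gene lists covering cell types, neighbouring tissue, transmitter systems, channels, stress, immune and cellular processes were tested with camera in limma, at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a region. A list was tested where at least 4 of its genes passed the filter. Camera compares a list with all other genes. Beside it stood camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance 1 way without comparing them with other genes. Member genes were counted as risen or fallen with adjustment over all genes and with adjustment over the list alone. A list score was the mean deviation of its genes from the region mean, on the log2 scale. Mitochondrially encoded transcripts were not analysed here.

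Named genes followed a rule: per region and direction, the 12 largest changes among genes past the adjusted threshold, or, where fewer passed, the genes of smallest p with a fold of at least 1.3; per list, up to 4 members past the threshold over the list alone, otherwise the 1 or 2 of smallest p; and up to 6 genes per difference between regions. Predicted genes and clone names were passed over. Some list members that this rule names are not reported here. The groups, tests, gene lists, this rule and the alternatives of pseudocount (0.1 or 1), filter (none or 2 RPKM), scaling (median of ratios or quantile), array weights, a myelin covariate, all libraries in 1 model and looser thresholds were fixed before the data were examined.

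The following were added after seeing the data. Voom, limma's method for counts, was run on the recovered reads. The GC slope of a library was the slope of its log2 values, relative to the region mean, on GC content. It was removed as a loess trend (span 0.3), entered as a covariate, or removed gene by gene with coefficients on the GC slope estimated within groups of the other 2 regions; the last is called the library-axis correction. Protein-coding genes were also tested alone, each library of a region was left out in turn, and 5 libraries were left out together (leaving out libraries that stand apart was planned, the rule was set afterwards) whose median correlation with their region lay more than 3 scaled median absolute deviations below the median (NAc SNI 7, PFC sham 13, PFC SNI 19, PAG sham 28 and PAG SNI 36).

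The method was tested on data simulated from the real means and depths. Of genes changed by a fold of 1.2, 1.3, 1.5 and 2, limma recovered 26.5%, 40.8%, 65.3% and 78% in NAc (15256 genes tested), 18.4%, 40%, 62% and 86% in PFC (15193) and 57.1%, 70%, 82% and 88% in PAG (15588). Unchanged genes made up 7 of 114, 1 of 107 and 11 of 166 calls. A planted list was called in each region with no other list. Genes were simulated independently of each other, so this cannot show how often lists of correlated genes are called without a change. Other splits of the real libraries called a median of 9 lists in NAc, 7 in PFC and 9 in PAG.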

Results

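The 36 libraries gave RPKM values for NAc, PFC and PAG, with 6 sham and 6 SNI libraries per region. NAc is a part of the ventral striatum engaged in reward and motivation, PFC takes part in the evaluation of pain, and PAG is a midbrain centre of descending pain control. Depth was 52.9 ± 8.54 M (mega) reads in NAc sham and 50.6 ± 11.1 in NAc SNI libraries (SD, n = 6), 50.2 ± 7.93 and 53.4 ± 5.82 in PFC, and 37.9 ± 3.67 and 34.8 ± 5.20 in PAG. Depth did not differ between sham and SNI by more than the spread of the libraries (exact permutation p = 0.693 in NAc, 0.396 in PFC and 0.275 in PAG; adjusted p = 0.693, 0.594 and 0.594).

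The regions were first compared in sham mice, to see whether the libraries carry the markers of the tissue they are labelled with. Slc17a7, the vesicular glutamate transporter of cortical neurons, had 473 ± 23.7 RPKM in PFC, 74.9 ± 56.4 in NAc and 2.25 ± 0.364 in PAG (SD, n = 6). Drd2, the dopamine D2 receptor gene, had 90.8 ± 12.2 RPKM in NAc, 1.28 ± 0.352 in PFC and 14.9 ± 1.22 in PAG. Slc17a6, the transporter of subcortical glutamatergic neurons, had 117 ± 5.42 RPKM in PAG against 2.43 ± 0.713 in NAc and 3.69 ± 0.823 in PFC, and Gata3, a transcription factor of midbrain GABAergic neurons, had 4.08 ± 0.168 RPKM in PAG and was near 0 elsewhere. Tph2 and Slc6a4, the enzyme and transporter of serotonin neurons, reached 153 ± 24.1 and 68.4 ± 12 RPKM in PAG. All 19 medium spiny neuron markers were at least 2-fold higher in NAc than in both other regions, as were 10 of 17 excitatory cortical markers in PFC, 10 of 15 midbrain and PAG markers and 9 of 11 monoaminergic and cholinergic markers in PAG. With limma, 1072 genes differed at least 2-fold between NAc and PFC (529 higher in NAc), 2034 between NAc and PAG (1030 higher in NAc) and 2360 between PFC and PAG (1210 higher in PFC), of 15639 tested.

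**Figure D1:**
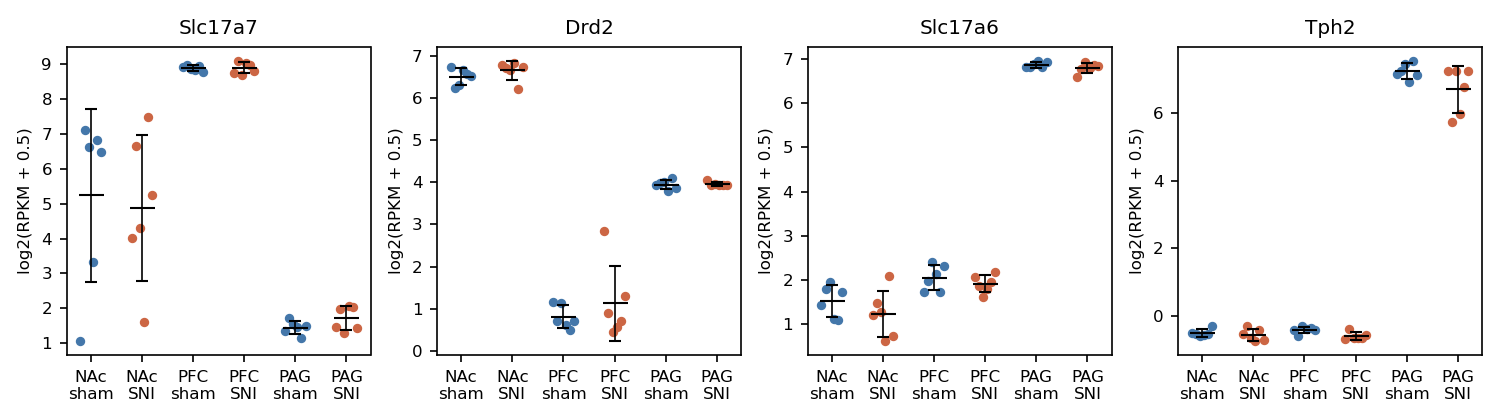
Expression of Slc17a7, Drd2, Slc17a6 and Tph2 as log2(RPKM + 0.5) in each library (points) by region and surgery, with group mean and SD (bars, n = 6). Each marker is highest in its own region, and Slc17a7 is scattered among NAc libraries.

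Slc17a7 was uneven among the NAc libraries, at 9.60, 97.8, 88.3, 113, 1.59 and 139 RPKM in sham libraries 1 to 6 and 178, 15.7, 19.2, 101, 37.7 and 2.53 in SNI libraries 7 to 12. Over the 12 NAc libraries, centred by group, the score of the excitatory cortical list went against that of the medium spiny neuron list (Pearson r = −0.740, permutation p = 0.00511; Spearman rho = −0.776, permutation p = 0.00412; r = −0.666 without sham 5 and SNI 12, the libraries farthest out).

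In NAc, the comparison of SNI with sham asked which transcripts differ in this reward region long after nerve injury. Btg2 (ENSMUSG00000020423; chromosome 1, 134075170 to 134079120), an antiproliferative gene induced by neuronal activity, had 4.81 ± 1.02 RPKM in sham and 2.93 ± 0.572 in SNI libraries (SD, n = 6; log2 fold change −0.62, SE 0.14). Tipin (ENSMUSG00000032397; chromosome 9, 64281581 to 64305424), a component of the replication fork protection complex, had 10.1 ± 0.290 and 7.65 ± 1.25 RPKM (−0.39, SE 0.08). Per2 (ENSMUSG00000055866; chromosome 1, 91415982 to 91459324), a core gene of the circadian clock, had 7.24 ± 1.07 and 10.1 ± 2.88 RPKM (0.42, SE 0.16), and Irs2, an adaptor of insulin signalling, 6.00 ± 0.599 and 8.61 ± 2.71 RPKM (0.43, SE 0.19). Btg2 and Tipin lay below the sham median in 6 of 6 SNI libraries, and Per2 and Irs2 above it in 5 of 6. None of these passed adjustment over all genes (adjusted p = 0.780 with limma). With the library-axis correction the log2 fold changes were −0.55 for Btg2, −0.30 for Tipin, 0.30 for Per2 and 0.18 for Irs2.

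The other genes of smallest p in NAc were Banp (log2 fold change 0.40), Capn11 (0.91, from 0.259 to 0.914 RPKM), Btbd17 (0.40), Fam222a (0.43) and Ppp1r35 (0.40) on the higher side. On the lower side were Mill2 (−0.51), Fbn1, which encodes fibrillin of the extracellular matrix (−0.41), and Oacyl (−0.38). Small RNA genes filled the remaining places, with Mir7-1, Mir1929, Mir365-1, Mir1963 and mmu-mir-6392 higher by 0.40 to 0.77 and n-R5s207, DQ267102, Mir453, Snord49a, mmu-mir-6913, mmu-mir-7664 and Snord16a at −0.93 to −0.39. Libraries of polyadenylated RNA capture such genes poorly. Each of these had the adjusted p = 0.780. With the library-axis correction Ppp1r35 went to 0.16, Fam222a to 0.23, Btbd17 to 0.23 and mmu-mir-6392 to 0.28. Banp (0.31), Capn11 (0.75), Mill2 (−0.49), Fbn1 (−0.40) and Oacyl (−0.36) kept more of their fold.

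With limma, 0 of 15264 genes passed the adjusted threshold in NAc, the lowest adjusted p being 0.0907; 660 had an unadjusted p under 0.05, where 763 are expected by chance, and voom gave 0 and 623. The looser count was 79 genes, 19 higher and 60 lower. Leaving out NAc SNI 7 raised the counts to 3 and 429 genes, and the looser count was 119 without NAc sham 6.

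Among the gene lists, 9 of 43 stood apart from the other genes in NAc, 8 upward and 1 downward. Heat shock and unfolded protein response genes lay higher in SNI, with 20 of 23 above 0 and a median log2 fold change of 0.10 (camera adjusted p = 8.16e-05; 0.771 with an estimated correlation). They included Sdf2l1 (0.35) and Pdia4 (0.22), which assist folding in the endoplasmic reticulum. Of 17 clock genes 14 lay above 0, led by Per2 (0.42) and Npas2 (0.22), with a median of 0.08 (adjusted p = 0.00112; 0.771 with an estimated correlation). Medium spiny neuron markers lay above 0 in 18 of 19 cases, with a median of 0.10, as for Gpr6 (0.32) and Drd2 (0.15) (adjusted p = 0.001; 0.771 with an estimated correlation); the cortical score of the libraries moved against this list, as given above. Fibroblast and meningeal genes lay below 0 in 13 of 13 cases, with a median of −0.52, as for the transporter Slc6a13 (−0.69) and Aebp1 (−0.52) (adjusted p = 0.0187; 0.771 with an estimated correlation). Their mean score was 2.09 in NAc sham 4 and between −0.60 and 0.80 in the other NAc libraries.

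The other upward lists in NAc were oligodendrocytes and myelin (13 of 22 above 0, Myrf 0.24 and Sox10 0.33; adjusted p = 0.0174), potassium and HCN channels (17 of 27, Kcnn3 0.19; 0.0187), glucocorticoid response (13 of 21, Tsc22d3 0.25 and Per1 0.27; 0.0480), chromatin remodelling (15 of 22, Kdm5c 0.13 but Kdm1a −0.12; 0.0187) and cytosolic ribosomal proteins (25 of 36, Rpl38 0.14; 0.0187). With an estimated correlation the adjusted p of ribosomal proteins was 0.843 and that of the other 4 was 0.771. With the library-axis correction oligodendrocytes turned downward (camera adjusted p = 0.770). Glucocorticoid response (0.122), chromatin (0.331) and ribosomal proteins (0.0837) were not called with it. The heat shock, clock, medium spiny, fibroblast and potassium channel calls held with it (at most 0.0103, and at least 0.637 with an estimated correlation). Under quantile scaling oligodendrocytes (0.0679), potassium channels (0.109), glucocorticoid response (0.109), chromatin (0.0708) and ribosomal proteins (0.157) were no longer called, and under median-of-ratios scaling glucocorticoid response (0.186) was not. Adjusted over the list alone, no gene rose and 1 fell, Btg2 of the immediate-early list (adjusted p = 0.0214); that list itself was not called (14 of 26 above 0; adjusted p = 0.552), and over all genes no member passed. The 34 lists not called had adjusted p of 0.0594 to 0.934, and in 18 of them median, mean and camera's direction differed in sign. Heat shock and clock calls held without each library in turn. The medium spiny call was lost without sham 2 (adjusted p = 0.103), and the fibroblast call without sham 3, sham 4, SNI 7, SNI 9 or SNI 11 (0.0546 to 0.614). The oligodendrocyte call was lost without sham 4, sham 5, SNI 7 or SNI 9 (0.0545 to 0.408), the potassium channel call without sham 4, SNI 7 or SNI 10 (0.0631 to 0.379), and the chromatin call without sham 4 or SNI 11 (0.0960 to 0.225). Ribosomal proteins were lost without sham 2, 5 or 6 or SNI 8, 9 or 12 (0.0759 to 0.415), and glucocorticoid response without sham 2, 4, 5 or 6 or SNI 7, 8, 10 or 12 (0.0545 to 0.291).

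In PFC, the comparison asked the same of a cortical area that takes part in the evaluation of pain. Npas4 (ENSMUSG00000045903; chromosome 19, 4984355 to 4990316), a transcription factor induced by neuronal activity, had 9.85 ± 2.70 RPKM in sham and 5.48 ± 0.812 in SNI libraries (SD, n = 6; log2 fold change −0.76, SE 0.17). Btg2 had 8.47 ± 2.49 and 5.02 ± 1.12 RPKM (−0.67, SE 0.19), Cyr61, a secreted matricellular protein, 2.47 ± 0.638 and 1.47 ± 0.405 RPKM (−0.59, SE 0.16), and Dusp1, a phosphatase of MAP kinases, 13.6 ± 3.92 and 8.68 ± 2.71 RPKM (−0.62, SE 0.24). All 4 lay below the sham median in 6 of 6 SNI libraries. None passed adjustment over all genes (adjusted p = 1 with limma). Adjusted over the list alone, Npas4 (adjusted p = 0.0177), Cyr61 and Btg2 (both 0.0363) fell among the immediate-early genes, and Dusp1 (0.136) did not pass.

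Capn11, a calpain protease gene, was at 0.381 RPKM in PFC sham and 1.16 in SNI libraries (0.96), and Ly6c1, an endothelial surface protein, at 14.8 ± 1.72 and 20.1 ± 5.81 RPKM (0.39). The other genes of smallest p with a fold of at least 1.3 in PFC were small RNA genes, an immunoglobulin segment, and ZEB2_AS1_2 and MIMT1_1, annotated as other RNA. Higher by 0.40 to 0.97 were mmu-mir-8116, Snord98, Mir5100, ZEB2_AS1_2, mmu-mir-7030, Mir681, Snord72, Mir744, n-R5s173 and Snord7, the last 2 with an unadjusted limma p of 0.0532 and 0.0567. At −1.04 to −0.40 were mmu-mir-8103, Snora23, MIMT1_1, n-R5s197, Mir129-1, Ighj4, n-R5s164 and Mir344b. Each had the adjusted p = 1.

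With limma, 0 of 15192 genes passed the adjusted threshold in PFC, the lowest adjusted p being 1; 220 had an unadjusted p under 0.05, where 760 are expected by chance, and voom gave 0 and 205. The looser count was 46 genes, 17 higher and 29 lower.

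In PFC 11 of 42 lists stood apart, 8 upward and 3 downward. Heat shock and unfolded protein response genes again lay higher in SNI, in 21 of 22 cases and with a median of 0.13, among them Xbp1 (0.22), a transcription factor of the unfolded protein response, and Creld2 (0.20) (camera adjusted p = 1.06e-07; 0.662 with an estimated correlation). Immediate-early genes lay lower, with 9 of 26 above 0 and a median of −0.15 (adjusted p = 0.000465; 0.662 with an estimated correlation). Their mean score differed by −0.21 (SE 0.16; exact permutation p = 0.206), and the call was lost without PFC SNI 19 (adjusted p = 0.501) and turned upward with array weights (0.943). All 22 oligodendrocyte genes lay above 0, with a median of 0.22, for example Trf (0.19) and Myrf (0.31), with SEs of 0.22 and 0.36 (adjusted p = 0.0206; 0.789 with an estimated correlation). Medium spiny markers lay above 0 in 15 of 16 cases, with a median of 0.14 (adjusted p = 0.000465; 0.662 with an estimated correlation), and their score was 0.789 in PFC SNI 24 and at most 0.0173 in the other SNI libraries; without SNI 24 the call was lost (0.585).

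**Figure D2:**
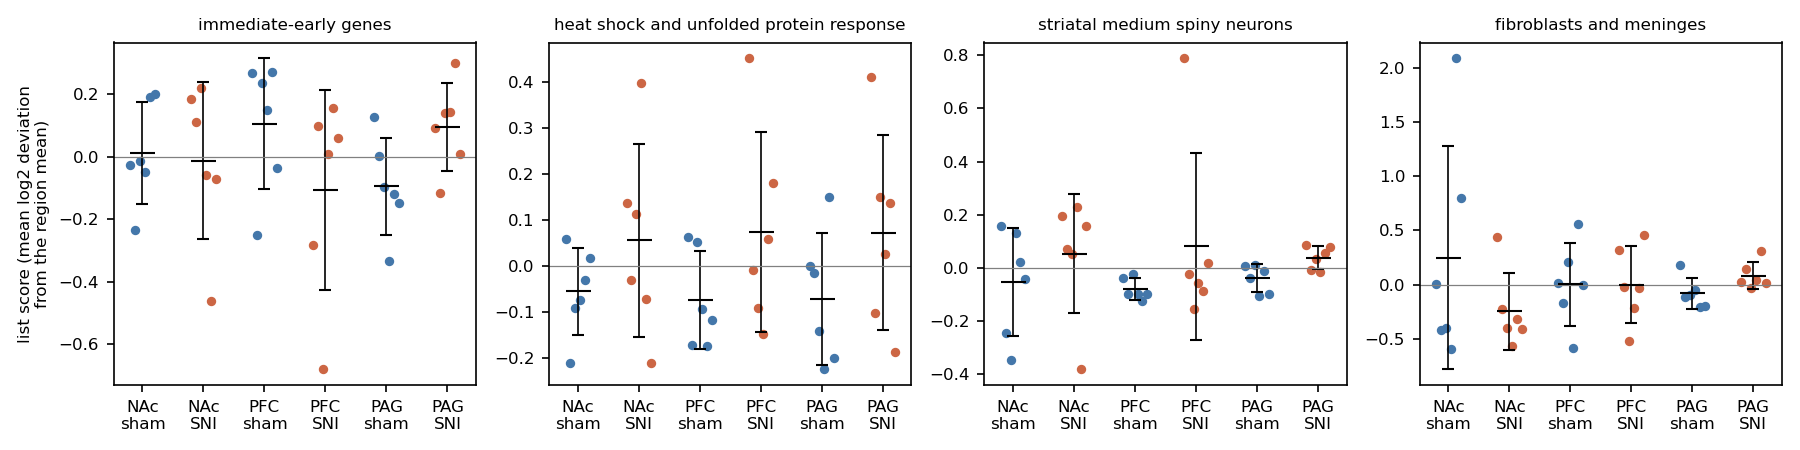
Scores of 4 gene lists (mean log2 deviation of the list's genes from the region mean) in each library (points) by region and surgery, with group mean and SD (bars, n = 6). PFC SNI 24 stands apart in the medium spiny list at 0.789 and NAc sham 4 in the fibroblast list at 2.09.

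The other upward lists in PFC were oligodendrocyte precursors (10 of 10 above 0, Gpr17 0.19; adjusted p = 0.0429), mural cells (10 of 12, Higd1b 0.20; 0.0324) and clock genes (14 of 17, Per2 0.35 and Cry1 0.13; 0.0357), each at 0.662 with an estimated correlation, and microglia (16 of 20, Csf1r 0.09; 0.0495) and ribosomal proteins (28 of 36, Rps23 0.11; 0.00483), at 0.702 with an estimated correlation. Red blood cell genes (1 of 8 above 0, Alas2 −0.22; 0.0192) and presynaptic release genes (4 of 23, Cplx2 −0.08; 0.0357) lay lower (both 0.662 with an estimated correlation). Under quantile scaling the microglia (0.0696) and presynaptic (0.0708) calls were lost. With array weights the microglia, mural and presynaptic lists turned to the other direction, as did microglia without the libraries in doubt. Over all genes no list member passed in PFC, and adjusted over the list alone none rose and 3 fell. The 31 lists not called had adjusted p of 0.0887 to 0.924; median, mean and camera's direction differed in sign for excitatory cortical, opioid, neuropeptide, interferon and cholesterol synthesis genes. Choroid plexus was not tested, since 3 of its genes passed the filter. The heat shock call held without each library in turn. The oligodendrocyte call was lost without sham 13, 16 or 17 or SNI 20, 23 or 24 (0.103 to 0.779), precursors without sham 13, 14 or 17 or SNI 19, 20, 23 or 24 (0.0576 to 0.716), and microglia without sham 13 or 14 or SNI 19, 20, 23 or 24 (0.106 to 0.948). Mural cells were lost without sham 13 or 17 or SNI 19, 20, 22, 23 or 24 (0.0518 to 0.919), red blood cells without sham 15 or SNI 19 or 24 (0.0564 to 0.164), and presynaptic genes without sham 13 or 18 or SNI 19, 20 or 24 (0.0684 to 0.614). Ribosomal proteins were lost without sham 13 or 17 or SNI 20 (0.0932 to 0.716) and clock genes without sham 15 or 18 or SNI 21, 22 or 23 (0.0580 to 0.230).

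In PAG, the comparison concerned a centre of descending pain control, and 5495 genes differed. Rpl36 (ENSMUSG00000057863; chromosome 17, 56613416 to 56614243), a ribosomal protein gene, rose from 8.67 ± 2.97 RPKM in sham to 39.3 ± 13.5 in SNI libraries (SD, n = 6; log2 fold change 2.13, SE 0.23; limma adjusted p = 5.91e-05). The metallothioneins Mt2 (ENSMUSG00000031762; chromosome 8, 94172664 to 94173568) and Mt1 (ENSMUSG00000031765; chromosome 8, 94179082 to 94180327), which bind metals and respond to stress, rose from 22.8 ± 3.60 to 75.6 ± 33.8 RPKM (1.63, SE 0.20; adjusted p = 9.03e-05) and from 43.9 ± 7.81 to 125 ± 50.1 RPKM (1.45, SE 0.19). Slc5a7 (ENSMUSG00000023945; chromosome 17, 54273590 to 54299034), the choline transporter of cholinergic neurons, fell from 11.7 ± 5.11 to 4.95 ± 3.59 RPKM (−1.36, SE 0.43; adjusted p = 0.0245). The rises held in 6 of 6 SNI libraries against the sham median, and Slc5a7 lay below it in 6 of 6. Slc5a7 was uneven within both groups, as its SDs show. Other neuronal markers were uneven too: over all PAG libraries Chat, a cholinergic gene, ranged from 0.361 to 6.16 RPKM and Cartpt from 58.1 to 359. Whether uneven dissection of PAG enters the fall of Slc5a7 was not tested.

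The other leading rises in PAG were Ccdc85b (1.88), Pcsk1n (1.47), which encodes the prohormone convertase inhibitor proSAAS, Fbll1 (1.45), Dpm3 (1.44), Mir219-2 (1.42), Mir132 (1.36), the synaptic adhesion gene Lrrc4b (1.28), Rps29 (1.27, from 22.3 ± 4.26 to 54.1 ± 8.52 RPKM) and Chpf (1.26), a chondroitin polymerising factor. The other leading falls were KCNQ1OT1_3 (−0.92), n-R5s87 (−0.87), Mirlet7c-2 (−0.78), Postn (−0.77), which encodes the matrix protein periostin, Chodl (−0.60), mmu-mir-6993 (−0.59), Spp1, which encodes osteopontin (−0.59, from 37.3 ± 13.4 to 23.8 ± 5.20 RPKM), Snora30 (−0.57), Mir344d-2 (−0.52), Spink8 (−0.40) and Cntnap3 (−0.39). With the library-axis correction Ccdc85b (−0.15), Pcsk1n (−0.54), Mir132 (−0.30) and Chpf (−0.01) changed sign, and Rpl36 went to 0.17, Mt2 to 0.32, Mt1 to 0.15, Fbll1 to 0.08, Lrrc4b to 0.09, Rps29 to 0.19, Mir219-2 to 0.48 and Dpm3 to 0.58. Several of the named falls kept about their size and SE with it, as Slc5a7 (−1.35, SE 0.43), Postn (−0.75), Mirlet7c-2 (−0.69), Chodl (−0.59) and Spp1 (−0.54), and mmu-mir-6993 grew to −0.92. Others shrank more, as KCNQ1OT1_3 (−0.76), n-R5s87 (−0.73), Snora30 (−0.31), Spink8 (−0.29) and Cntnap3 (−0.30). None of the named genes passed the adjusted threshold with the correction (limma adjusted p = 0.232 for Slc5a7 and 0.571 for Rpl36). For Slc5a7, Postn, Mirlet7c-2, Chodl and Spp1 the folds changed little, and the calls ended because fewer genes with small p raised the adjusted p. Slc5a7, Postn and Chodl were below the filter in PFC, and the correction can move genes low in its source regions little. Slc5a7 was not low in NAc, the other source region, with 11.5 ± 1.57 RPKM in sham libraries.

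With limma, 5495 of 15592 genes passed the adjusted threshold in PAG, 3360 up and 2135 down (61.1% up), with a median absolute log2 fold change of 0.22; voom called 5659. At a fold of at least 1.3 there were 1197 rises and 21 falls, and the looser count was 1266 genes (1219 higher, 47 lower). Under quantile scaling 42.1% of the calls were rises. Quantile and median-of-ratios scaling moved the median of all genes by at most 0.04 on the log2 scale, and no listed gene called with the deposited scaling changed sign under them.

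The libraries of the groups also differed in GC slope. In PAG the slope was 0.229 higher in SNI than in sham (log2 per 10 points of GC; exact permutation p = 0.00216, the smallest that 924 assignments can give; adjusted p = 0.00649), with sham libraries at −0.217 to −0.0246 and SNI libraries at 0.0359 to 0.218. The difference was 0.0860 in NAc (exact permutation p = 0.234; adjusted p = 0.351) and 0.0119 in PFC (0.909 and 0.909). Slopes also spread within the groups of NAc and PFC, with ranges of 0.242 to 0.379. They were −0.185, −0.131, −0.0653, 0.0449, 0.0215 and 0.0568 in NAc sham 1 to 6, −0.20, −0.0278, 0.0722, 0.152, 0.115 and 0.147 in NAc SNI 7 to 12, −0.262, −0.123, 0.0325, 0.0961, 0.104 and 0.117 in PFC sham 13 to 18 and −0.241, −0.0376, −1.18e-04, 0.112, 0.124 and 0.0787 in PFC SNI 19 to 24. The labels name no batch or order of preparation, and this spread enters the errors behind the counts of NAc and PFC. Across PAG genes, which are not independent replicates, fold change and GC content correlated at 0.65, and risen genes had a median GC content of 56.6% against 44.1% in fallen genes and 49.6% in all. A loess correction for GC left 2109 calls, 1343 of them genes called before with the same sign and 121 with the opposite sign; the library-axis correction left 21.

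**Figure D3:**
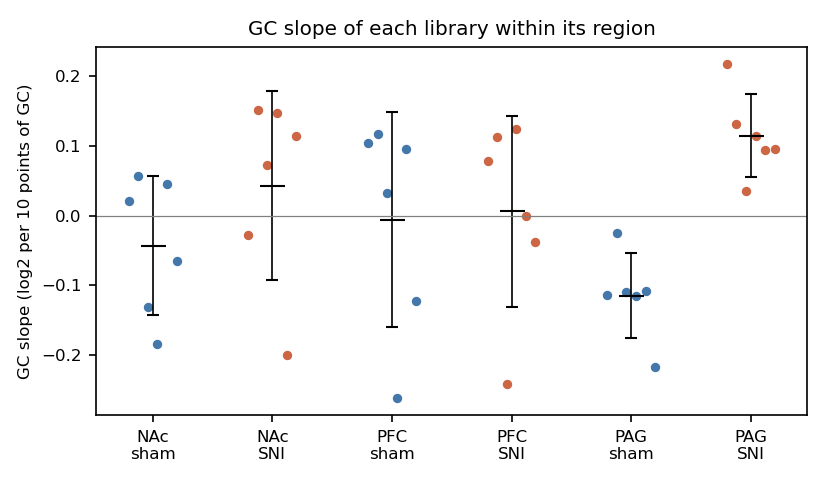
GC slope of each library (points; log2 per 10 points of GC, relative to the region mean) by region and surgery, with group mean and SD (bars, n = 6). The PAG groups do not overlap, with sham at most −0.0246 and SNI at least 0.0359.

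**Figure D4:**
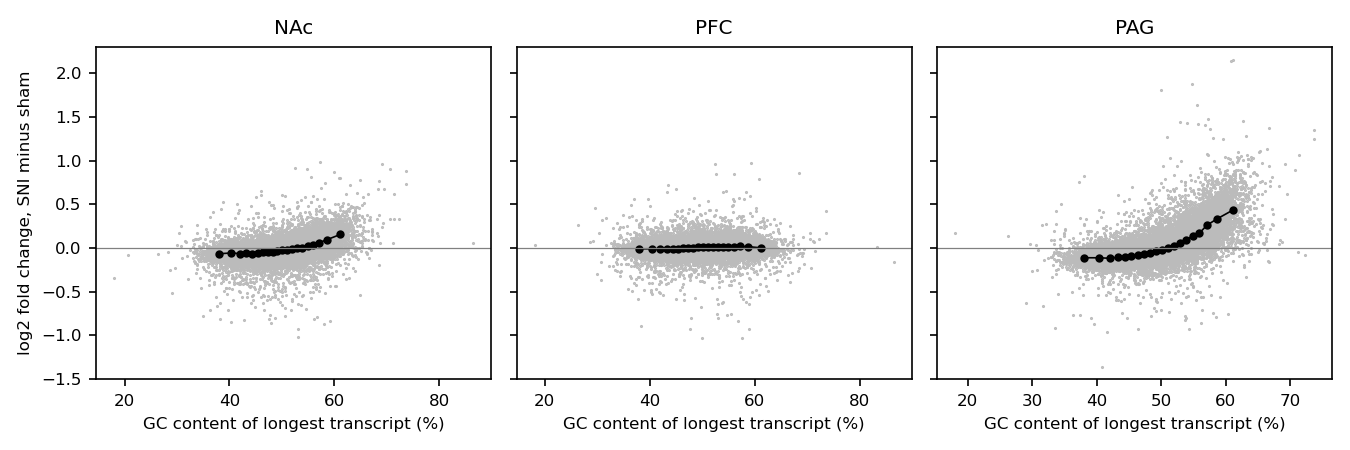
Log2 fold change of SNI against sham for each tested gene (grey points) by GC content of its longest transcript in percent, with medians of equal-sized bins (black), in NAc, PFC and PAG. The medians climb with GC content in PAG (correlation across genes 0.65) and to a lesser extent in NAc (0.42).

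Among the PAG lists, 2 of 43 stood apart, both upward. The member counts here and in the next list paragraphs stand beside 3360 rises and 2135 falls among all 15592 genes tested. A list with such shares moved as the other genes did. Folds are uncorrected unless stated. Of the members named in these paragraphs, only Foxj1 (higher) and Junb (lower) passed with the library-axis correction. That correction also called unchanged genes in simulated PAG libraries (37 of 184 calls), so both may be false calls. Of 36 cytosolic ribosomal protein genes 17 rose and 3 fell (18 and 4 adjusted over the list alone, camera adjusted p = 0.0141), including Rps29 (1.27), Rplp1 (1.07), Rpl37 (0.47) and Rpl13 (0.36). Of 31 nuclear genes of oxidative phosphorylation 15 rose and 4 fell (15 and 5 adjusted over the list alone, adjusted p = 0.0345), including Ndufs7 (1.25), Uqcr10 (0.75), Ndufb7 (0.72) and Ndufa2 (0.56), subunits of respiratory complexes. With an estimated correlation the adjusted p of each was 0.944. Both calls were lost without SNI 33 (0.164 each) and under the array weights, and the respiratory call also without sham 26, 27 or 30 or SNI 34 (0.0505 to 0.124) and under median-of-ratios scaling (0.0554). Neither was called with the library-axis correction (0.359 and 0.451), beside the GC slope difference of 0.229. The remaining 41 lists had camera adjusted p of 0.0719 to 0.987. Fry, which does not compare a list with other genes, called 12.

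Glial genes changed in PAG beside the GC slope difference of 0.229, without their lists standing apart from other genes. Of 22 oligodendrocyte genes 7 rose and none fell (6 and none adjusted over the list alone, adjusted p = 0.237), among them Sox10 (0.63, from 10.9 ± 0.722 to 17.3 ± 1.66 RPKM), the myelin gene Mbp (0.60), Olig1 (0.48) and the tight-junction gene Cldn11 (0.45). Of 20 microglial genes 8 rose and none fell (10 and 1 over the list alone, 0.237), among them C1qa (0.79) and C1qc (0.60) of complement, Tmem119 (0.59) and Selplg (0.31). Of 18 astrocyte genes 8 rose and 3 fell (8 and 4, 0.576), including Fgfr3 (0.39), Vim (0.34), Ntsr2 (0.22) and Aldh1l1 (0.20). Of 10 precursor genes 3 rose and 1 fell (3 and 1, 0.576), with Cspg4 (0.56) and Pdgfra (−0.11). Of 14 ependymal genes 2 rose (2 over the list alone, 0.576), Foxj1 (0.84), a regulator of motile cilia, and Rarres2 (0.31). Of 14 cytokine and innate immune genes 5 rose (5, 0.237), among them Rela (0.50) and Cx3cl1 (0.22). Of 19 interferon genes 2 rose (1, 0.750), H2-D1 (0.21) and Irf9 (0.19). Under quantile scaling 2 precursor genes rose and 2 fell, and 1 interferon gene rose and 3 fell. The direction of the interferon list turned downward with the library-axis correction (camera adjusted p = 0.0347, and 0.558 with an estimated correlation), as did those of oligodendrocytes (0.225) and precursors (0.321).

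Vascular and border tissues gave a similar picture at the same GC slope difference of 0.229. Of 17 endothelial genes 5 rose and 2 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.907), with Cldn5 (0.45) and Egfl7 (0.42) up and Tek (−0.20) down. Of 12 mural genes 3 rose (2, 0.366), including Cspg4 (0.56) and Notch3 (0.36). Of 12 fibroblast genes 5 rose (5, 0.267), including Ptgds (0.67) and Islr (0.47). Of 12 choroid plexus genes 1 fell, Prlr (−0.22), and none passed over the list alone (0.540). Of 8 red blood cell genes 2 rose and 1 fell (2 and 2, 0.907), with the haemoglobin gene Hba-a1 (0.74) up. Of 5 neutrophil and T cell genes 1 fell, Trac (−0.27) (1, 0.987); the list had a positive median and mean but a downward direction in camera, which turned upward under quantile and median-of-ratios scaling. Of 19 matrix and perineuronal net genes 6 rose and 1 fell (6 and 1, 0.237), among them Lamb2 (0.73), Col4a2 (0.69) and Bcan (0.53). Under quantile scaling 4 endothelial genes rose and 6 fell, 2 red blood cell genes rose and 2 fell, and 6 matrix genes rose and 5 fell. The fibroblast list turned downward with the library-axis correction (camera adjusted p = 0.00435, and 0.558 with an estimated correlation), as did mural (0.0521) and endothelial cells (0.318).

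Neuronal identity genes of PAG were also mixed, with the GC slope 0.229 higher in SNI. Of 16 midbrain and PAG neuron genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.907), with Sox14 (0.38), Gata2 (0.37) and Gata3 (0.35) up and Gad2 (−0.16) down. Of 12 monoaminergic and cholinergic genes 1 fell, Slc5a7 (−1.36), and none passed over the list alone (0.237). In this list Chat (−0.93; adjusted p = 0.0540) and Tph2 (−0.54; 0.112) did not pass. Tph2 was 52.7 RPKM in PAG SNI 31 and 62.2 in SNI 34, and above the sham median in 3 of 6 SNI libraries. Of 13 GABAergic interneuron genes 3 rose and 2 fell (3 and 4, 0.907), with Slc32a1 (0.56) and Sst (0.43) up; camera's direction was downward and turned upward under quantile scaling. Of 17 medium spiny markers 5 rose (5, 0.371), including Adora2a (0.45) and Rasd2 (0.28), and of 13 excitatory cortical markers 3 rose (2, 0.371), including Nrgn (0.76) and Cux2 (0.34). Of 12 thalamus and colliculus genes 4 rose and 1 fell (5 and 1, 0.265), with Barhl2 (0.39), Calb2 (0.21) and Prkcd (0.21) up and Rora (−0.16) down. Of 11 septum and hypothalamus genes 1 rose, Prdm16 (0.26) (1, 0.834). Median and mean differed in sign for the midbrain list. Under quantile scaling 3 GABAergic interneuron genes rose and 4 fell, and 1 septum and hypothalamus gene rose and 1 fell. The medium spiny list turned downward with the library-axis correction (camera adjusted p = 0.00435, and 0.381 with an estimated correlation), as did septum and hypothalamus (0.225).

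Receptors and peptides of pain circuits differed in both directions in PAG, as did all genes there, beside the GC slope difference of 0.229. None of these lists stood apart from other genes. Of 15 opioid system genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.750), with the nociceptin precursor Pnoc (0.67), Ogfr (0.34) and Arrb2 (0.18) up and Rgs7 (−0.24) down. Of 10 endocannabinoid genes 4 rose (4, 0.576), the synthetic enzymes Dagla (0.63) and Daglb (0.12) and the degrading enzymes Mgll (0.26) and Faah (0.17). Of 21 neuropeptide genes 3 rose (2, 0.987), including Pnoc (0.67) and Sst (0.43). Of 13 dopamine signalling genes 2 rose and 3 fell (2 and 3, 0.750), with the monoamine oxidase gene Maoa (−0.22) down. Of 18 serotonin and noradrenaline receptor genes 2 rose and 1 fell (1 and none, 0.689), Adra2c (0.24) being the 1 past the list alone. Of 12 neurotrophin genes 3 rose and 1 fell (3 and 1, 0.750), with Vgf (0.70) and Cntfr (0.62) up and the receptor gene Ntrk2 (−0.12) down. The median of the neuropeptide and neurotrophin lists was below 0 and their mean above it. Under quantile scaling 3 opioid system genes rose and 3 fell, 3 neuropeptide genes rose and 2 fell, and 1 serotonin and noradrenaline receptor gene rose and 3 fell. With the library-axis correction camera's direction turned downward for neuropeptides (adjusted p = 0.561) and neurotrophins (0.758).

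Synaptic and channel genes moved in both directions in PAG at this GC slope difference of 0.229, and none of their lists stood apart from other genes. Of 19 GABA receptor and transport genes 2 rose and 10 fell (2 and 12 adjusted over the list alone, adjusted p = 0.0719), with the chloride transporter gene Slc12a5 (0.32) up and the receptor subunit gene Gabrq (−0.29) down. Of 22 sodium and calcium channel genes 3 rose and 8 fell (3 and 8, 0.371), with Cacna1h (0.43) and Cacna1g (0.35) up and Cacna2d3 (−0.21) and Nalcn (−0.17) down. Of 20 ionotropic glutamate receptor genes 5 rose and 6 fell (5 and 6, 0.750), with Cacng8 (0.62) up and Gria4 (−0.18) down. Of 21 metabotropic receptor and scaffold genes 9 rose and 3 fell (9 and 6, 0.750), with Grm4 (0.66) and Shank3 (0.56) up. Of 26 potassium and HCN channel genes 5 rose and 4 fell (5 and 4, 0.799), with Hcn3 (0.50) up and Kcnd2 (−0.10) down. Of 23 presynaptic genes 6 rose and 3 fell (6 and 3, 0.750), with Stx1a (0.46) up and Sv2b (−0.22) down. Of 22 RGS and G protein genes 6 rose and 5 fell (6 and 6, 0.661), with Gnaz (0.28) up and Rgs7 (−0.24) down. Both glutamate lists, the potassium channel list and the RGS list had a median below 0 and a mean above it. Under quantile scaling 8 metabotropic and scaffold genes rose and 8 fell, 5 potassium channel genes rose and 5 fell, 6 presynaptic genes rose and 5 fell, and 6 RGS and G protein genes rose and 9 fell. With the library-axis correction camera's direction turned upward for GABA receptors (adjusted p = 0.318) and potassium channels (0.346) and downward for metabotropic and scaffold genes (0.798).

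Activity, stress and regulatory genes were counted in PAG with the GC slope 0.229 higher in SNI, and none of their lists stood apart from other genes. Of 23 immediate-early genes 8 rose and none fell (9 and none adjusted over the list alone, adjusted p = 0.113), including Per1 (0.61), Junb (0.55), Klf2 (0.49) and Arc (0.44). Junb was low, at 0.326 RPKM in PAG sham and 0.738 in SNI libraries, and above the sham median in 6 of 6 SNI libraries. Its log2 fold change was 0.04 with GC loess (limma adjusted p = 0.887) and −0.98 with the library-axis correction (0.0467). Its direction is thus not settled. Of 22 glucocorticoid response genes 5 rose and 2 fell (5 and 1, 0.267), with Mt2, Mt1 and Per1 up and Crhbp (−0.29), which encodes the CRH-binding protein, down. Of 17 clock genes 7 rose and 1 fell (7 and 1, 0.237), including Per2 (0.40), Dbp (0.29) and Tef (0.17). Of 24 heat shock and unfolded protein response genes 3 rose (3, 0.361), Cryab (0.41), Dnajb5 (0.20) and Ddit3 (0.15). Of 23 histone deacetylase and DNA methylation genes 12 rose and 2 fell (12 and 7, 0.237), including Mbd3 (0.86), Hdac7 (0.52) and Sirt2 (0.38). Of 21 chromatin remodelling genes 8 rose and 1 fell (8 and 1, 0.237), including Kmt2d (0.49), Kdm6b (0.43) and Ehmt2 (0.37). Of 19 cholesterol synthesis genes 4 rose and 3 fell (4 and 3, 0.541), including Mvk (0.47) and Srebf2 (0.39). Under quantile scaling 5 immediate-early genes rose and none fell, 10 histone deacetylase and methylation genes rose and 7 fell, 5 chromatin genes rose and 3 fell, and 4 cholesterol genes rose and 4 fell. Chromatin remodelling turned downward in camera with the library-axis correction (adjusted p = 0.750).

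The difference of the SNI effects between regions was tested directly. Mab21l2, a developmental gene expressed in the dorsal midbrain, had log2 fold changes of 0.56 in PAG, 0.08 in NAc and 0.04 in PFC, Gata3 of 0.35, −0.00 and 0.01, and Barhl2 of 0.39, 0.01 and −0.00. Gata3 and Barhl2 were at most 0.0712 RPKM in each NAc and PFC library, so that with a pseudocount of 0.5 their fold there is near 0 by construction. Ier2, an immediate-early gene, had 0.26 in NAc and −0.54 in PFC. The other genes of smallest p were n-R5s207, Gstm4, Fbxo5, Timm21 and Hist1h4i between NAc and PFC, n-R5s207, Dnajc17 and Odf3b between NAc and PAG, and Nudt3, Ankrd35 and Sfrp5 between PFC and PAG. With limma, 0 of 15639 genes passed for each of the 3 differences, with lowest adjusted p of 0.999 (NAc and PFC), 0.139 (NAc and PAG) and 0.0582 (PFC and PAG). At an unadjusted p under 0.05 there were 178, 1405 and 2779 genes, where 782 are expected, and voom also called 0 for each. Between PFC and PAG 5 genes passed with a pseudocount of 1, 11 without a filter, 84 without the libraries in doubt and 3712 with array weights. Between NAc and PAG 4 passed with a pseudocount of 1 and 4 without a filter. At the pseudocount of 0.5 and the filter of 0.5 RPKM with all libraries at equal weight, genes called in PAG are not shown to respond differently there.

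Across genes, which are not independent replicates, the SNI fold changes correlated at 0.60 between NAc and PAG (covariance 0.0167), 0.26 between NAc and PFC (0.00304) and 0.12 between PFC and PAG (0.00237). Of 100 relabellings of the libraries, 2, 28 and 57 gave a correlation as large in size. Genes with an unadjusted p under 0.05 and the same sign in a pair of regions numbered 304 in NAc and PAG (144 expected of independent lists), 31 in NAc and PFC (4.29 expected) and 34 in PFC and PAG (47.6 expected), against 4, 1 and 10 of opposite sign. Of the 100 relabellings 1, 14 and 10 gave as many of the same sign, with highest counts of 380, 268 and 418. With the library-axis correction the correlation of NAc and PAG was 0.046.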

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

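The tests by thinning to equal depth and by the share of neurons were chosen beforehand. Leaving out 1 library was added after the data were seen, before its own values were. The tests by GC content, GC slope and library axis, the relation of the cortical and medium spiny scores, the exact tests of list scores and the counts of other splits were chosen only after the results were seen. Single libraries stood apart from the other 5 of their group in 23 of 200 Dixon tests (11.5%), where chance gives about 1 in 20.

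PAG SNI 36 was far above the other PAG SNI libraries for 9 of the leading rises: Rpl36 (66.2 RPKM against 28.4 to 37.5), Ccdc85b (8.23 against 3.13 to 4.70), Mt2 (143 against 53.8 to 75.8), Pcsk1n (16.8 against 4.54 to 6.52), Mt1 (226 against 92.4 to 115), Dpm3 (4.93 against 1.92 to 2.41), Lrrc4b (32 against 16.7 to 21.6), Rps29 (70.8 against 47.1 to 54.1) and Chpf (13.7 against 6.24 to 7.75). PAG SNI 31 had mmu-mir-6993 at 2.72 RPKM (others 1.29 to 1.67).

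NAc SNI 7 had low scores for medium spiny neurons (−0.382, others 0.0511 to 0.231), chromatin remodelling (−0.148, others 0.0136 to 0.0998), ribosomal proteins (−0.308, others 0.0343 to 0.205) and clock genes (−0.121, others 0.0513 to 0.145). NAc SNI 8 had a high fibroblast score (0.436, others −0.567 to −0.223), and PFC SNI 24 a high medium spiny score (0.789, others −0.155 to 0.0173). Per2 was 9.32 RPKM in NAc sham 5 (others 6.40 to 7.17), Tipin 10.6 in NAc sham 1 (others 9.81 to 10.1), and mmu-mir-6913 0.873 in NAc SNI 12 (others 0 to 0.292). Snord7 was 9.28 RPKM in PFC SNI 19 (others 3.25 to 5.10), MIMT1_1 15 in PFC sham 14 (others 7.90 to 9.93), and n-R5s197 0.340 in PFC SNI 22 (others 0.779 to 0.994). PFC SNI 20 had 64.7 M reads (others 49.5 to 54.4).

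The 5495 genes called in PAG were weighed first. Depth is argued against as the cause, since thinning every library to the smallest depth left 5229 calls, and so is a smooth GC trend as the whole cause, since 2109 calls were made after a loess correction. A library axis that also varies within groups of NAc and PFC may account for most of the calls: with its coefficients from those regions removed, 21 were left, and the median log2 fold change of the called genes went from 0.31 to 0.04 for rises and from −0.16 to −0.02 for falls. Rpl36 went from 2.13 (SE 0.23) to 0.17 (SE 0.10), while 362 of 3339 rises and 273 of 2121 falls kept their sign and at least 0.5 of their fold, among them Slc5a7 (−1.36 to −1.35). For these the axis stays open, since how many would keep it through error in the coefficients was not computed and genes low in NAc or PFC can be moved little. An effect of SNI along the same axis cannot be told apart from it, because the GC slope, with a difference of 0.229, lay higher in every SNI than in every sham library of PAG. New PAG libraries from sham and SNI mice, prepared in mixed order, would separate the 2. Slc5a7 also varied widely within its groups (11.7 ± 5.11 RPKM in sham and 4.95 ± 3.59 in SNI libraries), and uneven dissection was not tested for it.

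The lower immediate-early list in PFC, with Npas4 and Btg2, was weighed second. That call rests on 1 library, since the adjusted p was 0.501 without PFC SNI 19, and its direction turned with array weights (0.943). A smaller share of neurons stays open, as the excitatory score differed by −0.00055 (SE 0.05) and the gap of the 2 scores by 0.21 (SE 0.14). An effect of SNI also stays open and cannot be told apart from spread between libraries, as the exact permutation p of the list score was 0.206. In situ counts of Npas4 per neuron in more mice would be a test.

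The higher medium spiny list in NAc, with Gpr6 and Drd2, was weighed last. Cortical tissue at the edge of the dissection may enter, since the cortical and medium spiny scores, centred by group, went against each other (r = −0.740, n = 12). Being within groups, that relation cannot show whether cortical tissue differed between SNI and sham. The call was lost without NAc sham 2 (camera adjusted p = 0.103). An effect of SNI stays open and cannot be told apart from spread between libraries, as the exact permutation p of the medium spiny score was 0.377. Dissections checked for Slc17a7 before sequencing would be a test.

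Other splits of the same libraries were counted, 100 per result with the real one included. For PAG, no other counted split was as large for the 5495 genes (1 of 100 with the real one, highest other 2574). The same held for the looser count of 1266 (1 of 100, highest other 766). Chance is thus unlikely for these 2 counts but not excluded, since only 100 of 462 possible splits were counted. For the 2 lists of PAG, 94 of 100 splits were as large (highest other 19). The split with 2574 genes had the largest GC slope difference of the other splits, 0.179. Chance was not excluded in NAc for the looser count of 79 (40 of 100, highest other 616) or the 9 lists (57 of 100, highest other 17), nor in PFC for the looser count of 46 (76 of 100, highest other 599) or the 11 lists (28 of 100, highest other 20). Splits with several times the real count, as for both looser counts, point to a structure of the samples, which was not tested further. Where the real count was 0, all 100 splits are as large by construction, which says nothing about chance. This holds for NAc with limma (highest other 1, 660 at an unadjusted p under 0.05 and 0 with voom) and PFC with limma (highest other 0, 220 at an unadjusted p under 0.05 and 0 with voom). It also holds for the differences between regions with limma and voom (178, 1405 and 2779 at an unadjusted p under 0.05), with highest others of 4 (NAc and PFC), 2301 (NAc and PAG) and 4880 (PFC and PAG). For the sham regions no other counted split was as large (1 of 100 splits each, the real one), with 1072 genes against 572, 2034 against 1096 and 2360 against 1242.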

How the results depend on the processing

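Voom, the GC corrections (loess, slope covariate, library axis), protein-coding genes alone and leaving out each library were chosen only after the data were seen; the other alternatives were planned. Where no cause is given below, the cause was not tested. Depth limited low genes, with 13.8 reads at 0.5 RPKM and 1 kb in the shallowest library. The counts between sham regions stayed within 1.5 times under the 9 alternatives run, while the correlation of NAc with PFC (0.260) ranged from 0.147 to 0.270 and that of PFC with PAG (0.119) from −0.0258 with the myelin covariate to 0.140 under the 11 run. No paired analysis was possible because the groups shared no replicate numbers. With the GC slope covariate the looser counts were 64 in NAc and 50 in PFC.

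In NAc the count of 0 genes with limma (660 at an unadjusted p under 0.05, voom 0) became 2 with array weights, 1 with the myelin covariate, 1 with GC loess, 3 without the libraries in doubt, 1 at an FDR of 0.1, and 0 to 3 with 1 library left out (3 without SNI 7). The looser count of 79 became 122 with a pseudocount of 0.1, 46 with 1, 30 at 2 RPKM, where fewer genes were tested, 329 with array weights, 20 for protein-coding genes, also fewer, 429 without the libraries in doubt, 660 without a fold minimum, and 54 to 429 with 1 library left out (429 without SNI 7, 119 without sham 6). The 9 lists became 4 under quantile scaling, 4 with GC loess, 5 without the libraries in doubt, 0 with an estimated correlation in camera, 0 with fry, and 5 to 11 with 1 library left out (5 without sham 4 or SNI 7). Oligodendrocyte genes turned downward with the library axis removed (adjusted p = 0.770 in camera).

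In PFC the count of genes was 0 with limma under each of the 28 alternatives (220 at an unadjusted p under 0.05, voom 0). The looser count of 46 became 76 with a pseudocount of 0.1, 91 without a filter, 11 at 2 RPKM, 87 with array weights, 71 with voom, 7 for protein-coding genes, 70 without the libraries in doubt and 220 without a fold minimum. The 11 lists became 5 without a filter, 7 at 2 RPKM, 5 with array weights, 5 with the myelin covariate, 7 with the GC slope covariate, 5 without the libraries in doubt, 0 with an estimated correlation, 0 with fry, and 4 (without SNI 24) to 17 (without SNI 21) with 1 library left out, with 5 without sham 13, 6 without SNI 19 or SNI 20 and 7 without sham 17 or SNI 23. With array weights microglia (adjusted p = 0.231 in camera), mural cells (0.80), immediate-early (0.943) and presynaptic genes (0.887) turned to the other direction, as did microglia without the libraries in doubt (0.901).

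In PAG the 5495 genes became 3337 with all 36 libraries in 1 model, 2109 with GC loess and 21 with the library axis removed. With 1 library left out they became 4234 to 6529. With the GC slope covariate in limma they became 0 (368 at an unadjusted p under 0.05 and a fold of 1.3, voom on uncorrected reads 5659). That covariate goes with surgery in PAG. It also left 0 of 6201 calls in simulated PAG libraries that had gene effects with a GC trend but no axis. The looser count of 1266 became 421 with GC loess, 368 with the slope covariate, 107 with the axis removed and 7170 without a fold minimum. The 2 lists became 10 without a filter, 1 at 2 RPKM, 1 under median-of-ratios scaling, 0 with array weights, 0 with the myelin covariate, 1 with GC loess, 12 with the slope covariate, 9 with the axis removed, 1 for protein-coding genes, 0 with an estimated correlation, 12 with fry, and 0 (without SNI 33) to 5 (without SNI 35) with 1 library left out, with 1 without sham 26, sham 30 or SNI 34. With the axis removed Ccdc85b (−0.15), Mir132 (−0.30), Chpf (−0.0129) and Pcsk1n (−0.54) changed sign, as did Pcsk1n (−0.0493) and Mir344d-2 (0.0885) with the slope covariate.

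For differences between regions the 0 genes with limma and voom (178, 1405 and 2779 at an unadjusted p under 0.05) became 1 without a filter for NAc and PFC. They became 4 with a pseudocount of 1 and 4 without a filter for NAc and PAG. For PFC and PAG they became 5 with a pseudocount of 1, 11 without a filter, 3712 with array weights, 1 with GC loess, 84 without the libraries in doubt and 1 at an FDR of 0.1. The NAc with PAG correlation was 0.0460 with the library axis removed.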

Other observations

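The genes and lists of this part were chosen after their values were seen, and so was the library-axis correction. With that correction 21 genes passed in PAG with limma, 17 higher and 4 lower in SNI, and 18 of them were also called without it. The same correction left 184 calls in simulated PAG libraries with the axis and 200 changed genes, 37 of them of unchanged genes. Those 37 outnumber the 21 genes called here, so any of the 21 may be a false call. Agt, the angiotensinogen gene expressed in astrocytes, had 62.7 ± 6.69 RPKM in sham and 96.1 ± 5.85 in SNI libraries (SD, n = 6; corrected log2 fold change 0.31, limma adjusted p = 0.0226). Foxj1 and Odf3b, genes of motile cilia, had corrected changes of 0.49 and 0.62 (0.84 and 0.85 uncorrected), the transcription factor genes Npas1 0.29, Mab21l2 0.50 and Barhl1 0.50, the secreted Wnt antagonist gene Sfrp5 0.54, and Nptx1, which encodes a neuronal pentraxin, 0.25. Nrn1, which encodes neuritin, was at 51.2 ± 2.64 and 50.5 ± 4.21 RPKM, with −0.02 uncorrected, 0.06 with GC loess and 0.37 corrected. Lower with the correction were C1ql1 (−0.45), Prima1 (−0.35), which encodes the membrane anchor of acetylcholinesterase, and Junb (−0.98) and C1qtnf4, the last 2 of which rose without it. These 2 were low in PAG, Junb at 0.326 RPKM in sham and 0.738 in SNI libraries and C1qtnf4 at 0.341 and 1.12. With GC loess their log2 fold changes were 0.04 and 0.10 (limma adjusted p = 0.887 and 0.632).

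Among the PAG lists the same correction gave a downward direction for monoaminergic and cholinergic neurons and, turned from upward, for medium spiny neurons and fibroblasts and an upward one for thalamus and colliculus (camera adjusted p = 0.00435 each). The monoaminergic and cholinergic list was lowest in PAG SNI 31 and SNI 34, where Tph2 was 52.7 and 62.2 RPKM. It also gave upward directions for clock (0.0160), presynaptic (0.0162), endocannabinoid (0.0268) and excitatory cortical genes (0.0474) and a downward one, also turned, for interferon response (0.0347). With an estimated correlation none of these 9 lists was called, with adjusted p of 0.381 to 0.655. In simulated PAG libraries with the axis and 200 changed genes, limma called 5139 genes without a correction (4969 of them unchanged), 1847 with GC loess (1686 unchanged), 64 with the slope covariate (2 unchanged) and 184 with the axis removed (37 unchanged). The simulated axis had the same coefficients in every region. It therefore cannot show how well coefficients of NAc and PFC carry over to PAG. In other simulated libraries PAG had no axis but gene effects, the observed folds shuffled among genes of like GC content. These effects thus kept the GC trend and were not free of a relation to the axis. The counts there were 6201, 3550, 0 and 5377.

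Per2 had positive log2 fold changes in NAc (0.42), PFC (0.35) and PAG (0.40), and passed adjustment over all genes in PAG (limma adjusted p = 0.00163) but not in NAc (0.780) or PFC (1). With the library-axis correction its log2 fold change in PAG was 0.06 (adjusted p = 0.805), beside the GC slope difference of 0.229. Capn11 was higher in NAc (0.91) and PFC (0.96) without passing.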
